A study of Mus musculus with 36 samples.

How the data were processed

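Mouse embryonic stem cells were profiled by ChIP-seq in serum medium with LIF on a feeder layer, after 24 hours in 2i medium with LIF, and after 3 passages in 2i. 2i is a serum-free medium that holds 2 kinase inhibitors and keeps the cells in a more uniform, naive state. The cells were KH2, an established mouse line, except for 1 Nanog sample from cells that lack DNA methyltransferases, called TKO in the labels. Chromatin was fixed with formaldehyde, sheared by sonication and precipitated with an antibody on magnetic beads, and the libraries were sequenced on an Illumina instrument, per the labels' protocols. The labels list 36 samples. 14 peak lists, from 22 of these samples, were analysed here: 6 for Nanog, 3 for Sox2, 2 for Oct4 and 3 for the histone mark H3K4me3. The 3 H3K27me3 samples, the 1 whole-cell extract and the 10 RNA samples were not analysed here. The labels give the molecule of the Sox2 libraries as RNA, although these libraries carry an antibody and their files hold peaks. They were treated as ChIP-seq.

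The submitters' processing notes name BWA 0.5.7, Bowtie 0.12.7, MACS2, TopHat, Cufflinks 2.2.1 and Cuffdiff, and the genome build mm9. Which aligner made which list is not given in the sources used here. The peak names speak of pooled replicates and a control, but for 6 of the 14 lists, both of Oct4, the 3 of Nanog lot 2 and Sox2 at 3 passages, the labels hold 1 sample, so what the authors pooled is not given in the sources used here. Each condition had 1 list and no value per replicate. Each deposited peak carries the authors' fold enrichment, a ratio over the control, and a q-value, which the authors give as −log10 q. A further deposited column gives the offset of the peak summit, which was not used. Fold enrichment and −log10 q were used to rank, filter or describe peaks within a list. In addition, peaks of one list were set against the lowest −log10 q of another. The −log10 q of 2 lists need not be on one scale. Read depth per library is unknown, since the lists hold no counts.

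Each list is a selection from a longer set of calls. The peak numbers in the names run to 117690 in the Nanog 24 h list of lot 1, which holds 41755 peaks. The rule of selection is not given in the sources used here. The lowest −log10 q differed between lists, from 3.69 for Sox2 at 24 h to 86.4 for Oct4 in serum, so the lengths of 2 lists do not rest on one threshold. For this reason each count of regions was also given with both lists at the length of the shorter one, keeping the peaks with the largest −log10 q. The 14 lists held no duplicated peak positions, and no 2 lists were identical.

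Peaks on chromosomes 1 to 19, X and Y were used. Peaks of the lists compared were merged into regions wherever they overlapped by at least 1 bp, and a region was called in a list if it held a peak of it. The 13 comparisons were between culture conditions for each factor or mark, between KH2 and TKO cells, and between 2 lots of the Nanog antibody in the same condition. Lot 1 was used for serum, 24 h and 3 passages. Lot 2 was used for GFP-high serum cells, 24 h and TKO cells at 24 h. No test between conditions was possible for the counts, because each condition had 1 list. The number of peaks of one list that met the other was set against 100 circular shifts within chromosomes (one-sided, smallest p 0.0099, with the last peak end over all lists as the chromosome's length).

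Regions called only in the second list were compared with those called only in the first for overlap with another list by Fisher's exact test, two-sided, with 95% intervals of the odds ratio from 1000 resamples of 10 Mb genome blocks. Of the 30 such tests, adjusted together by Benjamini and Hochberg's method, the Nanog tests of lot 1 against serum H3K4me3 and against Sox2 were planned before the data were examined. The p-values printed below for these tests are the unadjusted ones. Regions are not replicates, so these p-values and intervals describe the lists at hand and not the spread between cultures. Shares carry exact binomial 95% intervals (Clopper-Pearson), which cover counting error only.

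The regions named for each comparison were taken from the 5 only in the first list and the 5 only in the second with the highest fold enrichment in their own list, by a rule fixed beforehand. Other named regions are marked as chosen after their values were seen. Positions are mm9, counted from 1. The annotation at hand is of the assembly GRCm38.p6, another build, so no region was assigned to a gene, exon or intron, and the planned tests of gene lists were not run. H3K4me3, a mark found mainly at active promoters, was used as a stand-in for promoter location.

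Alternatives were a minimum −log10 q of 10, lists of equal length, an overlap of 50% of the shorter peak, and joining peaks up to 1000 bp apart. Limiting both lists to the larger of their lowest −log10 q, leaving out chromosomes 6 and 8, and leaving out X and Y were added after the data were seen. The code was tested on a simulated pair of lists with 15000 regions. It returned the 2000, 9000 and 4000 regions that had been made only in the first, in both and only in the second, and an odds ratio of 4.18 for the 3.86 put in. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1 for a check of overlaps on the simulated lists.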

Results

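The binding of the pluripotency factors Oct4, Sox2 and Nanog, and the histone mark H3K4me3, was mapped in mouse embryonic stem cells as they were moved from serum medium to 2i, to ask how factor binding was rearranged when the cells entered the ground state. Each condition was represented by 1 list of peaks called by the authors, and 6 of the 14 lists have 1 sample in the labels. On the main chromosomes the Nanog lists of antibody lot 1 held 25534 peaks in serum, 41755 after 24 h of 2i and 33185 after 3 passages. With lot 2 there were 26415 peaks in serum cells labelled GFP-high, 21893 in KH2 cells after 24 h of 2i and 38518 in TKO cells, which lack DNA methyltransferases, after 24 h of 2i. The Sox2 lists held 13128 peaks in serum, 15310 at 24 h and 8749 at 3 passages. Oct4 had 5011 peaks in serum and 7820 at 24 h. H3K4me3 had 19287 peaks in serum, 17438 at 24 h and 18947 at 3 passages. There were no replicate lists, so no difference between conditions could be set against the spread between replicates, and fold enrichments are the authors' values for single peaks.

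The first comparison asked where Nanog bound after 24 h of 2i. With lot 1, 21307 regions were called in both serum and 24 h 2i, 20377 were called only at 24 h and 4095 only in serum. Of the serum regions, 83.9% were still called at 24 h. The strongest sites were shared, and 996 of the top 1000 serum peaks met a 24 h peak. At equal length the counts came to 8038 only at 24 h and 7946 only in serum, with 17462 in both. For lists of 1 factor, here and below, equal length brings the numbers on both sides close together by construction. Such counts do not tell whether length made the difference. Of the peaks at 24 h, 21378 met a serum peak, against a mean of 560 under circular shifts (one-sided permutation p = 0.0099, the smallest possible).

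The strongest Nanog region called at 24 h and not in serum lay on chromosome 14 from 55071171 to 55072052, with a fold enrichment of 65.4. It was also called for Nanog at 3 passages, for Oct4 and Sox2 at 24 h, and for Sox2 at 3 passages, but for neither Oct4 nor Sox2 in serum. Next came regions on chromosome X from 53655743 to 53656962, with a fold of 59.8, and on chromosome 10 from 82784182 to 82784947, with a fold of 58.6, both of which also held a Sox2 peak at 24 h. All 3 were nevertheless called with lot 2 in GFP-high serum cells. Among regions only in serum, the one on chromosome 17 from 41041068 to 41042197 had a fold of 49.0 and was otherwise called only for Sox2 in serum. The 3 serum-only regions with the highest folds, led by chromosome 19 from 23169059 to 23170281 with a fold of 88.2, were called in every other Nanog list and in all Oct4 and Sox2 lists. Their absence was therefore particular to the 24 h list of lot 1.

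Regions called for Nanog at only one time differed in the partner factors they carried. A serum Sox2 peak overlapped 16.7% of the serum-only regions and 3.79% of the 24 h-only regions (odds ratio 0.197, 95% interval 0.175 to 0.220, Fisher's exact p = 3.76e-170). With the Sox2 peaks of 24 h the order turned around, at 4.71% of serum-only and 10.3% of 24 h-only regions (odds ratio 2.32, 1.97 to 2.73, exact p = 3.19e-33). Oct4 followed Sox2. Serum Oct4 peaks met 4.20% of serum-only and 1.17% of 24 h-only regions, and 24 h Oct4 peaks met 2.71% and 4.74%. Serum H3K4me3 peaks overlapped 11.2% of 24 h-only and 8.03% of serum-only regions (odds ratio 1.45, 1.29 to 1.64, exact p = 5.09e-10). At equal length this difference reversed, with 6.30% of 24 h-only and 12.3% of serum-only regions.

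**Figure D1:**
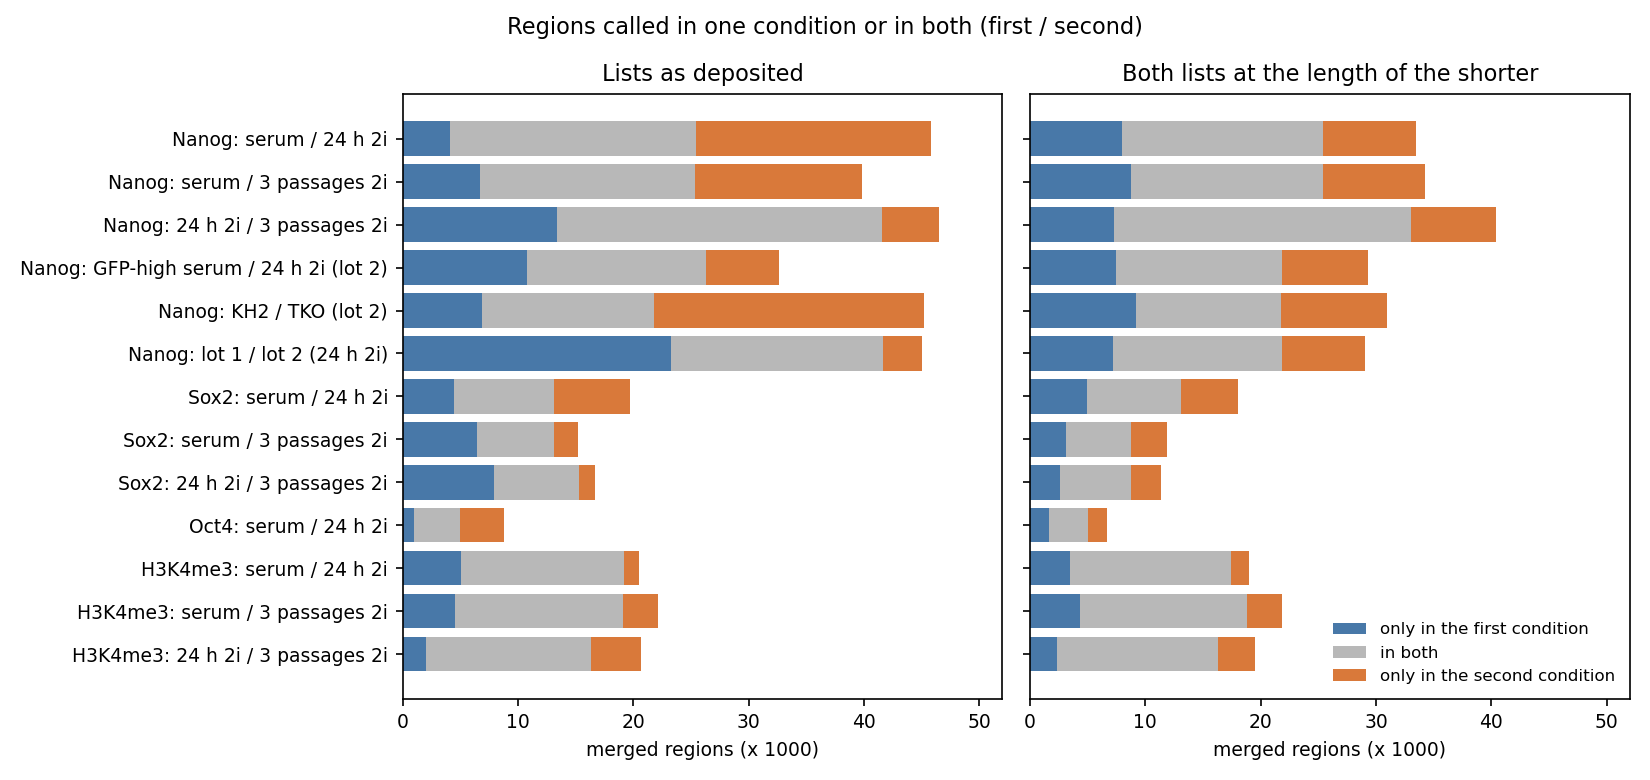
Merged regions, in units of 1000, called only in the first condition, in both, or only in the second, for the 13 comparisons, with the lists as deposited (left) and both at the length of the shorter (right). The excess of 24 h-only over serum-only Nanog regions, 20377 against 4095, became 8038 against 7946 at equal length.

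The second antibody lot gave counts in the opposite order with the lists as deposited. From GFP-high serum cells to 24 h of 2i, 15521 regions were called in both, 10811 only in serum and 6275 only at 24 h. At equal length there were 7486 and 7449. The strongest 24 h-only region, on chromosome 1 from 87544287 to 87544849 with a fold of 48.7, was called in all lists of Nanog in 2i and in neither serum list. So was the region on chromosome 16 from 92541164 to 92541730, with a fold of 48.3. The strongest GFP-high-only region, on chromosome 2 from 98506175 to 98507688 with a fold of 70.6, was called in no other list and lies in a stretch of the mouse genome known for high signal in many ChIP-seq libraries. Serum Sox2 peaks met 23.2% of the GFP-high-only and 4.05% of the 24 h-only regions, the same order as with lot 1. The Sox2 peaks of 24 h met 18.2% of the GFP-high-only and 10.3% of the 24 h-only regions (odds ratio 0.516, 0.470 to 0.566), so the turn of the order seen with lot 1 was not seen with lot 2. In serum H3K4me3 the order was opposite to that of lot 1 as deposited, at 7.58% and 4.22%. At equal length the order was the same with both lots. Lot 2 then had 7.69% of GFP-high-only and 4.24% of 24 h-only regions, and lot 1 had 12.3% of serum-only and 6.30% of 24 h-only regions.

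The lots could be compared in 1 condition, although their 24 h lists differed in more than the lot. The labels hold 2 samples for lot 1 and 1 for lot 2. The lists held 26 and 0 peaks on Y, and 0 and 22 on unplaced contigs. After 24 h of 2i, 18356 regions were called with both lots, 23252 only with lot 1 and 3425 only with lot 2. At equal length 50.3% of all regions were shared between lots (95% interval 49.7 to 50.9), against 52.2% between serum and 24 h with lot 1 and 49.0% between GFP-high serum and 24 h with lot 2. Regions called as changed with both lots were next compared in their direction. Of the 20244 regions called at 24 h and not in serum with lot 1, 2899 were also called at 24 h and not in GFP-high serum with lot 2, or 14.3% (95% interval 13.8 to 14.9 over genome blocks), against 10.5% of all other regions called in any of the 4 lists (odds ratio 1.42, 1.35 to 1.501, exact p = 2.77e-38). Another 2206 of the 20244 went the other way with lot 2. The 10.5% is not a background rate, because a region without a lot 1 call is counted only if lot 2 called it. The odds ratio and its p-value therefore do not measure agreement between the lots. Regions lost with lot 1 were lost with lot 2 in 942 cases and gained in 97.

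After 3 passages the Nanog list kept part of what was seen at 24 h. Of 20260 regions called at 24 h and not in serum, 10039 were called at 3 passages, or 49.6% (95% interval 48.9 to 50.2). Of 4083 regions called in serum and not at 24 h, 86.5% (85.4 to 87.5) were also not called at 3 passages. Of all serum regions, 73.5% were called at 3 passages. Regions only in serum against 24 h had a median fold of 9.43, against 13.1 for shared ones, so the 86.5% does not measure lasting loss. Serum and 3 passages shared 18643 regions, with 14497 only at 3 passages and 6730 only in serum, or 8895 and 8768 at equal length. The serum-only region with the highest fold in that comparison, 69.7 on chromosome 14 from 9569194 to 9569953, was still called at 24 h and was otherwise called only for Sox2 in serum. The 4 next in order were likewise called for Nanog at 24 h and for Sox2 in serum. At 3 passages the leading new region, on chromosome 2 from 168250762 to 168251768 with a fold of 58.0, was called in all 2i lists of Nanog and in GFP-high serum. Between 24 h and 3 passages, 28129 regions were shared, 13412 were called only at 24 h and 4952 only at 3 passages, or 7294 and 7332 at equal length.

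Nanog binding in TKO cells was compared with KH2 cells at 24 h of 2i. The lists differ in cell line as well as in DNA methyltransferases, so the comparison does not single out DNA methylation. In both lists 14933 regions were called, in TKO cells alone 23389, and in KH2 cells alone 6846. At equal length the last 2 came to 9200 and 9194, and 40.6% of regions were shared (40.1 to 41.2), the lowest share among the 13 comparisons. H3K4me3 peaks of 24 h overlapped 11.4% of the TKO-only and 2.45% of the KH2-only regions (odds ratio 5.11, 4.25 to 6.19, exact p = 1.64e-140). A like contrast in H3K4me3 was seen between the 2 lots in KH2 cells at 24 h, at 13.6% of regions only with lot 1 and 3.65% of those only with lot 2. Sox2 peaks of 24 h overlapped 4.97% of TKO-only and 27.5% of KH2-only regions (odds ratio 0.138, 0.127 to 0.150), and 13.2% and 3.82% of the regions of only lot 1 and only lot 2. The H3K4me3 and Sox2 lists were of KH2 cells, so what these regions held in TKO cells was not measured. The KH2-only regions included strong sites. The 5 with the highest folds, from 98.6 on chromosome 2 from 111623990 to 111624961 to 69.0 on chromosome 5 from 110111715 to 110112601, were each called in every other KH2 Nanog list and for Sox2 at 24 h. Of the 5 strongest TKO-only regions, 3 were on chromosome 6, the first from 34708887 to 34709571 with a fold of 103.9. Another, on chromosome 4 from 143992560 to 143994190 with a fold of 72.6, was called in no other Nanog list. Chromosome 6 held 9.50% of TKO peaks (9.21 to 9.80) and 5.98% to 6.17% of the peaks of the 5 KH2 Nanog lists. For chromosome 8 the shares were 6.51% and 4.71% to 5.07%, and for chromosome X 2.14% and 3.07% to 3.83%.

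**Figure D2:**
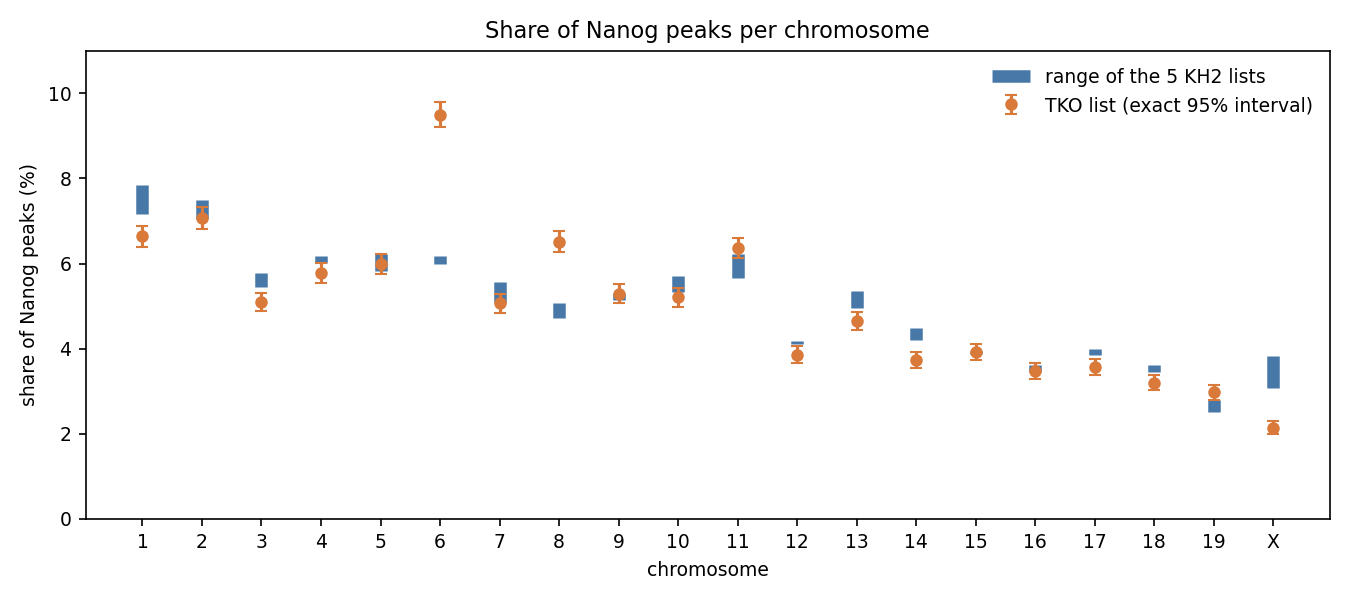
Share of Nanog peaks (%) on each chromosome in the TKO list (points, with exact 95% binomial intervals) and in the 5 KH2 Nanog lists (bars, lowest to highest). Chromosome 6 stands at 9.50% in TKO cells and at no more than 6.17% in any KH2 list.

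The Sox2 lists of serum and of 24 h of 2i also differed. In serum and at 24 h, 8648 regions were shared, 4467 were called only in serum and 6602 only at 24 h, or 4924 and 4897 at equal length. Serum H3K4me3 peaks overlapped 20.5% of the serum-only, 10.5% of the shared and 3.33% of the 24 h-only regions (odds ratio of 24 h-only over serum-only 0.134, 0.112 to 0.159, exact p = 2.99e-189). This order held at equal length, with 20.004% and 3.21%. The 24 h-only regions more often carried Oct4 at 24 h, in 25.7% against 6.85% of serum-only regions (odds ratio 4.71, 4.11 to 5.31). Overlap with the serum Oct4 list was not tested. Nanog at 24 h covered 72.2% of 24 h-only and 66.3% of serum-only regions, while serum Nanog covered 47.6% and 71.2% (odds ratio 0.368, 0.335 to 0.400). The strongest serum-only Sox2 region, on chromosome 17 from 12155482 to 12156146 with a fold of 31.9, was called again at 3 passages, as were 3 of the next 4. At 24 h the autosomal region that led the new Sox2 sites lay on chromosome 17 from 57642472 to 57643397, with a fold of 37.7. It was called for Nanog in all lists, for Oct4 in both and for Sox2 at 3 passages. The other 4 leading regions were on X and Y, and were otherwise called only for Nanog in serum and at 24 h with lot 1. These 3 lists held 21 to 42 peaks on Y and 0 on unplaced contigs. Whether they were aligned to the same set of sequences as the others is not given in the sources used here. A difference of processing was therefore not excluded, at these 4 regions or in any comparison of these lists with another list. The lists differed in their lowest −log10 q, 17.3 in serum and 3.69 at 24 h, and 92.6% of the 24 h-only regions lay below the lowest serum value. With both lists limited to the serum value, an alternative added after the data were seen, 486 regions were called only at 24 h and 9266 only in serum.

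At 3 passages the Sox2 list shared 6620 regions with serum, had 2107 of its own and lacked 6488. At equal length 3140 were only at 3 passages and 3147 only in serum, and 81.3% of the regions new in the full list lay below the lowest serum −log10 q. Nanog at 3 passages was present at 87.4% of the regions new to 3 passages and at 60.6% of those found only in serum (odds ratio 4.52, 3.96 to 5.22). Serum Nanog was present at 55.5% and 75.9% (odds ratio 0.396, 0.355 to 0.438). The serum H3K4me3 overlap was 4.08% and 17.9%. The leading serum-only region, on chromosome 8 from 116407762 to 116408363 with a fold of 51.3, was still called for Sox2 at 24 h. New at 3 passages and also called for Sox2 at 24 h was the region on chromosome 17 from 35700480 to 35701310, with a fold of 19.1, which held an H3K4me3 peak at 3 passages only. The 24 h and 3 passage lists shared 7355 Sox2 regions, with 7915 only at 24 h and 1388 only at 3 passages, or 2638 and 2646 at equal length. Of 6590 Sox2 regions gained at 24 h, 19.4% (18.4 to 20.3) were called at 3 passages, and of 4462 lost, 87.7% (86.7 to 88.6) were also absent. Of all serum Sox2 regions, 50.5% were called at 3 passages. Sox2 regions only in serum against 24 h had a median fold of 7.99, against 11.6 for shared ones, so the share absent does not measure lasting loss. The share kept is limited by the lists, since the lowest −log10 q was 3.69 at 24 h and 7.52 at 3 passages, and 66.0% of the 7915 regions lay below the latter. With a minimum of 10, 2138 regions were called only at 24 h. The 3 passage list rests on 1 sample in the labels.

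The Oct4 list lengthened in 24 h of 2i. There were 4018 shared regions, 3780 called only at 24 h and 976 only in serum, and at equal length 1642 and 1639. Of the 24 h-only regions 67.4% held a 24 h Sox2 peak and 86.1% a 24 h Nanog peak, against 41.7% and 67.3% of the serum-only regions (odds ratios 2.89, 2.501 to 3.33, and 3.00, 2.56 to 3.52). With the serum lists the order was opposite, at 40.1% and 57.5% for Sox2 (odds ratio 0.495, 0.425 to 0.574) and 68.1% and 72.4% for Nanog (0.814, 0.702 to 0.938). Serum H3K4me3 overlapped 5.79% of 24 h-only and 15.9% of serum-only regions (odds ratio 0.326, 0.257 to 0.418, exact p = 6.73e-22), and 4.69% and 14.3% at equal length. The new Oct4 region with the highest fold, 110.8 on chromosome 8 from 30282121 to 30282871, was bound by Nanog in all lists but by Sox2 only in 2i. The next, with a fold of 94.6 on chromosome 10 from 10647494 to 10648182, held Sox2 at 24 h and lacked Nanog in serum with lot 1. The strongest serum-only Oct4 region, on chromosome 1 from 67007158 to 67008041 with a fold of 50.8, kept Sox2 and Nanog at 24 h.

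**Figure D3:**
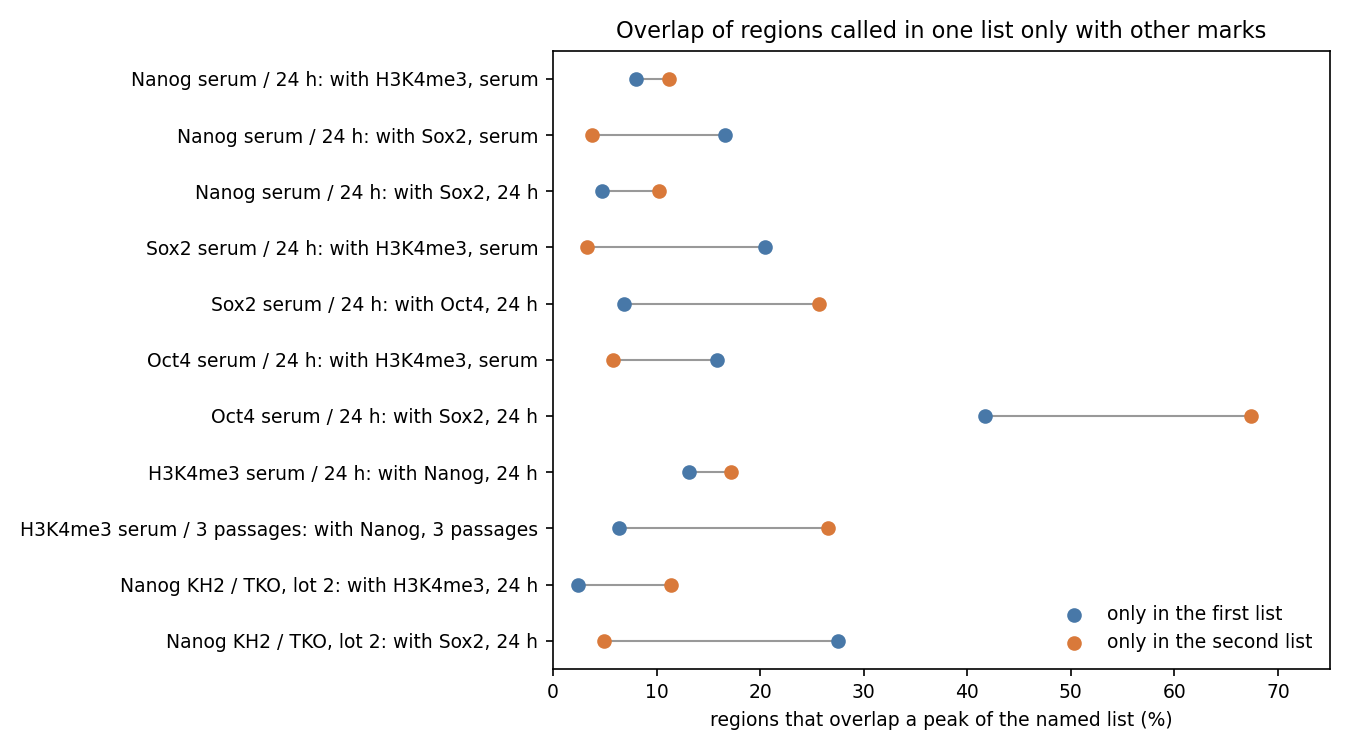
Percent of regions called only in the first list (blue) or only in the second (orange) that overlap a peak of another factor or mark, for 11 pairs of a comparison and a list. The overlapped lists are all of KH2 cells, also for the TKO comparison. Sox2 and Oct4 regions found only at 24 h met serum H3K4me3 at 3.33% and 5.79%, against 20.5% and 15.9% of regions found only in serum.

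All 3 factors were called together at 3604 regions in serum and at 5800 at 24 h, or 72.2% and 74.4% of the Oct4 regions. Nanog was taken from the lists of lot 1. Circular shifts gave means of 0.77 and 2.77. With all 6 lists at the length of the shortest the counts were 1989 and 2104. Of the regions with all 3 factors, 2939 were so in both conditions. Another 2850 had all 3 at 24 h and fewer in serum, and 666 had all 3 in serum and fewer at 24 h. Of the 2850, 1242 lacked only Oct4 in serum, 806 had only Nanog and 269 had none. The strongest of the 269 by mean rank was nevertheless called for Nanog with lot 2 in GFP-high serum cells. Of the 666, 40 had none at 24 h. H3K4me3 of the same condition overlapped 12.0% (10.9 to 13.1) of the regions with all 3 factors in serum and 7.83% (7.15 to 8.55) at 24 h. These shares rest on different H3K4me3 lists. The serum list held 19287 peaks with a median width of 1505 bp, and the 24 h list 17438 with 1121 bp. The lower share at 24 h was not separated from the fewer and narrower peaks.

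The H3K4me3 lists were more alike than those of the factors. Serum and 24 h shared 14164 regions, 5072 were called only in serum and 1286 only at 24 h. At equal length 73.3% of regions were shared (72.7 to 74.0), above each of the 10 comparisons of factors. At that length 3494 were only in serum and 1562 only at 24 h. Both lists then held 17438 peaks, so this gap comes from how many peaks joined 1 region and is not a net loss of peaks. The same holds for the other equal-length counts of H3K4me3. By −log10 q, 3 of the 5072 serum-only regions ranked in the top 25% of the serum list, while by fold the 5 leading ones all did. The strongest serum-only region, with a fold of 35.8 on chromosome 11 from 4846272 to 4848550, was called again at 3 passages. In contrast, chromosome 19 from 5796158 to 5803666, with a fold of 28.8, was called in neither 2i list, although it held Nanog and Sox2 in both media. A pair of adjoining regions on chromosome 7, from 52377708 to 52379847 and from 52380221 to 52384263, led those new at 24 h, with folds of 20.3 and 24.5. Both were called at 3 passages and overlapped Nanog peaks in lot 1 2i lists but in neither serum list. The lowest −log10 q was 4.91 at 24 h and 10.5 in serum, and with a minimum of 10 only 128 regions were left that were called only at 24 h.

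After 3 passages H3K4me3 shared 14575 regions with serum, 3008 were new and 4567 were no longer called, or 3087 and 4309 at equal length. Of the 4567, 33.3% lay below the lowest −log10 q of the 3 passage list, while 0 of the 3008 lay below that of serum. The larger number no longer called was thus not separated from the difference in lowest −log10 q, nor from how many peaks joined 1 region. The new regions overlapped a Nanog peak of 3 passages in 26.6% of cases, against 6.35% of those found only in serum (odds ratio 5.33, 4.66 to 6.26, exact p = 3.85e-131), and a Sox2 peak of 3 passages in 11.2% against 2.01%. Equal length gave 26.6% and 6.22% for Nanog. Only the 3 passage lists of Nanog and Sox2 were tested here. For Sox2 and Oct4 regions, where partner lists of both conditions were tested, the order turned with the serum list. These shares therefore do not tell whether the new H3K4me3 regions held more Nanog or Sox2 in both media. Chromosome 1 from 39711273 to 39714458, with a fold of 71.8, ranked 11 in the list at 3 passages and was also called at 24 h, but not in serum. The reverse was seen on chromosome 16 from 23106330 to 23113500, which ranked 2 in serum with a fold of 51.6, was called at 24 h and was not called at 3 passages. On chromosome 17 from 40630963 to 40632723 the mark was new in 2i at a region bound by Oct4, Sox2 and Nanog in every list. Of the 5022 regions lost at 24 h, 73.7% (72.5 to 74.9) were also absent at 3 passages, and of the 1241 gained, 304 were called there, or 24.5% (22.1 to 26.99). Of all serum regions, 76.1% were called at 3 passages. Those only in serum against 24 h had a median fold of 6.26, against 16.2 for shared ones. Between 24 h and 3 passages 14256 regions were shared, 2063 were called only at 24 h and 4335 only at 3 passages, or 2370 and 3177 at equal length. Of the 2063, 94.6% lay below the lowest −log10 q of the 3 passage list, and with a minimum of 10 the count was 345.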

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

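The equal-length counts in this part were planned, while their use as tests of length and of lot, and the dropped test, were chosen after the results were seen.

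The change of Nanog lists from serum to 24 h of 2i went in opposite directions with the 2 antibody lots. With lot 1 there were 4.98 regions only at 24 h for each region only in serum, and with lot 2, from GFP-high serum, 0.580. The difference was not tested, since each arm had 1 list. The length of the lists stays open. At equal length lot 2 had 0.995 regions only at 24 h for each only in serum and lot 1 had 1.01, but where most regions hold 1 peak of each list, lists of one length give near-equal numbers whatever the cause, and all 10 comparisons of factors did so. An earlier test of length, run before this one and dropped, used the direction among regions called as changed with both lots. Its odds ratio for the same direction was 12.8 (95% interval 10.4 to 16.0), which does not depend on the totals and so says nothing of their order. The lot or the sort for GFP stays open too, because lot and sort change together in the serum lists and cannot be told apart, and the 24 h lists of the 2 lots shared 50.3% of regions at equal length, about as many as lists of different conditions. An effect of 2i on the sites that moved alike also stays open. So does a difference in processing or in the number of samples between the lists of the 2 lots, which was not tested.

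Peaks outside the chromosomes used were found in several lists. On the mitochondrial genome there were 12 peaks, in 4 Nanog lists, with a highest fold of 7.90 in TKO cells. On unplaced contigs there were 241 peaks in 11 lists. They were left out of every comparison.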

How the results depend on the processing

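Limiting both lists to the larger lowest −log10 q and leaving out chromosomes were chosen after the data were seen. No paired analysis was possible because each condition has 1 list of peaks with no value per replicate. The planned gene list tests were not run, because no annotation of build mm9 was at hand. Counts within 1.5 times of the main count were taken as kept. All 26 counts were kept with an overlap of 50% of the shorter peak, and all 26 when peaks up to 1000 bp apart were joined. Those of TKO against KH2 were kept without chromosomes 6 and 8, and those of Sox2 in serum against 24 h without X and Y. A minimum −log10 q of 10 removed peaks in only 5 of the 13 comparisons, and in the other 8 it tested nothing. It moved Sox2 in serum against 24 h to 7454 regions only in serum and 1392 only at 24 h, Sox2 only at 3 passages against serum to 1278, Sox2 only at 24 h against 3 passages to 2138, H3K4me3 only at 24 h against serum to 128, and H3K4me3 only at 24 h against 3 passages to 345. The larger of the lowest values gave 9266 and 486 for Sox2 in serum and at 24 h, and 116 for H3K4me3 only at 24 h.

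Equal length moved 15 of the 33 results tried with it and reversed 1. For lists of 1 factor it brings the numbers on both sides close together by construction. Nanog of lot 1 came to 7946 regions only in serum and 8038 only at 24 h, to 8895 only at 3 passages against serum, and to 7294 only at 24 h against 3 passages. TKO-only regions came to 9200, and the lots to 7241 and 7185. Sox2 came to 3147 only in serum against 3 passages, and to 2638 only at 24 h and 2646 only at 3 passages. Oct4 came to 1639 and 1642. Regions with all 3 factors came to 1989 in serum and 2104 at 24 h. The share of 24 h Nanog regions kept at 3 passages moved to 60.3%. The odds ratio of H3K4me3 overlap for Nanog regions only at 24 h over those only in serum reversed from 1.45 to 0.478 (Fisher's exact p = 7.61e-40), and the cause was not tested. The Sox2 overlaps and the odds ratio of regions gained with both lots kept their direction and their side of 0.05. Depth could not be compared, since the lists carry no counts.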

Other observations

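The tests of chromosome copies, of list length on chromosome 8 and of turnover between lists in this part were chosen after the results were seen, while the bounds for the tests of list length on chromosome 6 and of deletions were written before their values were known.

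At 269 regions no factor was called in serum and Oct4, Sox2 and Nanog were all called at 24 h of 2i. By mean rank over the 3 lists the strongest, chosen after the values were seen, was on chromosome 14 from 55070898 to 55072052, with folds of 43.4 for Oct4, 21.0 for Sox2 and 65.4 for Nanog. The Nanog peak of this region was also called with lot 2 in GFP-high serum cells. Others of the 269 stood on chromosome 9 from 111660317 to 111661244 and on chromosome 13 from 88136987 to 88137768, with Oct4 folds of 44.4 and 39.3.

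H3K4me3 regions narrowed in the 2i lists. At the 13236 regions called in all 3 lists, the median length covered was 1864 bp in serum, 1471 bp at 24 h and 1658 bp at 3 passages. The covered length was below that of serum at 88.7% of them at 24 h and at 68.8% at 3 passages. Peaks longer than 4 kb numbered 589, 165 and 365. Peak width moves with depth and with the threshold, and neither is known here.

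Peaks on chromosome Y were uneven between lists. Sox2 at 24 h had 42, Nanog of lot 1 had 26 at 24 h and 21 in serum, Sox2 in serum had 12, and no other list had more than 3. The first 3 of these lists had 0 peaks on unplaced contigs and the fourth had 3, while the other lists had 6 to 42. Whether all lists were aligned to the same set of sequences is not given in the sources used here.

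The larger share of TKO Nanog peaks on chromosomes 6 and 8 was weighed against the length of the TKO list and the number of copies of the chromosomes. The length is argued against by 2 values: with the TKO list at the length of the KH2 list, chromosome 6 still held 9.13% of peaks (8.75 to 9.52), above the highest KH2 list at 6.17%, and chromosome 8 held 6.10% (5.78 to 6.42), above the highest at 5.07%. A gain of chromosome 6 in the TKO cells is a candidate explanation. Among regions called in both lists, those on chromosome 6 ranked a median of 7.76 percentiles higher in the TKO list than in the KH2 list, outside the range of −2.96 to 3.85 of the other autosomes without 8, and 60.0% of its 15 bins of 10 Mb (32.3 to 83.7) lay above the 90th percentile of those chromosomes' bins, short of the 75% asked for. On chromosome 8 the median was 2.36 and 23.1% of bins (5.04 to 53.8) lay above it, so neither gain was settled, and an effect of lost methylation was not tested.

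Strong sites were missing from the TKO list. Of 2709 regions in the top 25% of all 5 KH2 Nanog lists, 103 were not called in TKO cells, or 3.80% (3.11 to 4.59). When each KH2 list was left out in the same way, with the TKO list among the other 5, at most 0.404% were missing. KH2 lists thus seldom lacked such sites, but these sites were strong in TKO cells as well. The shares rest on unlike sets of regions and cannot decide on turnover between lines. The TKO list was longer than 4 of the other 5. The strongest missing region was on chromosome 9 from 46389643 to 46390772, and 94.2% of the 103 held Sox2 at 24 h in KH2 cells, against 98.4% of the strong regions that were called. Deleted stretches may account for some of them. A TKO peak lay within 50 kb of 58.3% of the missing regions (48.1 to 67.9), against 83.2% of the strong regions that were called, so long deletions were neither excluded nor shown. Loss of DNA methylation and the different origin of the line stay open and untested.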
